A study of Gloeophyllum trabeum and Trametes versicolor with 18 samples.

How the data were processed

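Transcript levels were measured by RNA sequencing in 18 libraries, 3 for each of 3 carbon sources in each of 2 fungi, *G. trabeum* and *T. versicolor*. Per the labels' protocols, RNA was extracted with TRIzol and a PureLink RNA mini kit and libraries were made with a NEBNext Ultra II RNA library kit. Whether the protocol kept strand was not given in the sources used here. Per the submitters' processing notes, kallisto 0.51.1 and DESeq2 1.48.2 were used, and the file headers are those of kallisto abundance tables. The transcript sets and genome builds against which reads were assigned were not given in the sources used here. For each library the authors deposited estimated counts per transcript, which kallisto divides between similar transcripts and which need not be whole. They also deposited TPM values, transcript lengths and effective lengths in the same tables. Estimated counts were used as the measurement, the effective lengths entered an alternative and a check described later, and the TPM values were not used for any result.

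Groups were taken from the sample labels. The tables hold 11880 transcripts for *G. trabeum* and 15606 for *T. versicolor*. All 11880 *G. trabeum* identifiers matched a reference gene table of assembly Glotr1_1, 11753 as coding transcripts and 127 as tRNA-type locus tags, and genes are named by its locus tags. Since the build behind the counts is not named, no coordinates are given, and the table was used only for names and for which genes neighbour each other. The table names no scaffolds, so a border was placed wherever the start position fell from one gene to the next, and neighbours were counted only between borders. *T. versicolor* genes carry the identifiers of the files. Neither the files nor the table pair identifiers with gene functions, so the gene lists by function and by protein motif that had been fixed before the data were examined could not be made, and ortholog pairs and list scores between the fungi could not be computed. Genes are therefore named by identifier alone. Of the *T. versicolor* models, 99.6% have lengths that are multiples of 3, so their length is a coding length.

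Estimated counts were rounded to whole numbers. Within each fungus, genes with low counts were removed with filterByExpr over the carbon sources, which left 10728 genes in *G. trabeum* and 13340 in *T. versicolor* and at least 99.9854% of the counts of each library. Libraries were scaled with TMM. All 9 libraries of a fungus were fitted in 1 model with the carbon source as the only term, using edgeR 4.0.16 (glmQLFit and glmQLFTest with robust estimation) in R 4.3.3. The 3 comparisons of each fungus were low-melanin necromass against glucose, high-melanin necromass against glucose, and high-melanin against low-melanin necromass. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that fungus and comparison. Standard errors of log2 fold changes were taken as the size of the fold change divided by the square root of its F statistic. CPM values use TMM-scaled library sizes, and principal components used log2 CPM with a prior count of 2. The 2 fungi were never put in 1 count model.

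Genes named for each comparison were chosen by a rule written before the data were examined. They are the 2 genes each way with the largest fold change among those called, with no overlap in CPM between the 3 libraries of one group and the 3 of the other, and with a mean of at least 10 CPM in the higher group. Chance alone gives no overlap for 10% of genes with 3 libraries against 3. The parts of the rule that need a gene name or a gene list could not be applied. A transcript with an estimated count further than 0.01 from a whole number in any library shares reads with similar transcripts. Transcripts with such a count in the library itself held 8.16% to 10.1% of its counts in *G. trabeum* and 2.55% to 3.52% in *T. versicolor*. Named genes with such a count in any library are marked as uncertain.

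Depth ranged from 18050313 to 26514709 estimated counts per library. In counts simulated from the real means, spreads and library sizes, with 200 genes changed by known folds in low-melanin necromass, the test was checked for each comparison. Each library was drawn independently with 1 spread per gene. A library that stands apart from its group, as in *G. trabeum* high-melanin necromass, was not simulated, so the shares may not hold for its comparisons. For low-melanin necromass against glucose it called 19.4% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 100% of those changed 4-fold in *G. trabeum* (10728 genes), with 10 unchanged genes called. In *T. versicolor* (13340 genes) these values were 16.4%, 77.6% and 97%, with 13 unchanged genes called. For high-melanin against low-melanin necromass they were 11.9%, 71.6% and 100% in *G. trabeum*, with 11 unchanged genes called, and 28.4%, 73.1% and 97% in *T. versicolor*, with 11 unchanged genes called. In the real data 54.1% to 62.8% of genes were called in every comparison but high-melanin against low-melanin necromass in *G. trabeum*. With 200 genes changed the cutoff on unadjusted p is stricter, so these shares may be too low for those comparisons.

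The mean fragment length behind the effective lengths differed between libraries. It was 291 to 344 bases on glucose, 249 to 274 on low-melanin and 267 to 293 on high-melanin necromass in *T. versicolor*. In *G. trabeum* it was 317 in glucose replicate 1 and 245 to 269 in the other libraries. TMM factors were 1.063 to 1.126 on glucose, 0.882 to 0.922 on low-melanin and 1.00 to 1.027 on high-melanin necromass in *T. versicolor*.

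Overlap between the comparisons that share glucose libraries was set beside 100 simulated data sets in which all 9 libraries were drawn from the glucose means with the fitted spread, so that both comparisons shared the same drawn glucose libraries. Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter and a stricter filter on low counts (at least 10 counts in every library of a group and a mean of 5 CPM), DESeq2 1.42.0, limma-voom (limma 3.58.1), a test beyond 2-fold (glmTreat), fits of only the 6 libraries compared, the replicate number as a block, the effective length as an offset, overlaps restricted to changes of at least 2-fold, and leaving out each library in turn. Scaling by library size alone, fragment length as a covariate, leaving out transcripts under 500 bases, thinning every library to the smallest, and counts of genes past 2-fold for each comparison were chosen after seeing the data. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.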

Results

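RNA sequencing was used to measure transcript levels in 2 wood-decay fungi grown in liquid culture on 3 carbon sources. *Gloeophyllum trabeum* (strain ATCC 11539) is a brown-rot fungus and *Trametes versicolor* (strain A1-ATF) is a white-rot fungus. Each was grown for 7 days in Highley's medium, a defined mineral medium, with 1% (w/v) glucose, with 0.45% (w/v) low-melanin fungal necromass or with 0.45% high-melanin fungal necromass. Necromass is dead fungal biomass, and melanin is a dark polyphenolic pigment of fungal cell walls. The carbon sources were therefore supplied at different concentrations. There were 3 libraries for each fungus and carbon source, 18 in all. Total estimated counts per library ranged from 18050313 to 26514709. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical. The study's title concerns the pathways by which such fungi break down dead fungal biomass and plant litter, and the design compares gene expression on the carbon sources within each fungus.

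Libraries separated by carbon source in both fungi. In *G. trabeum* the first principal component of log2 CPM held 79.2% of the variance and set the glucose libraries apart from all 6 necromass libraries. The second component held 8.52% and separated the necromass types, with high-melanin replicate 3 lying far from the other libraries of its group. In *T. versicolor* the first component held 55.7% and the second 35% of the variance, and the 3 carbon sources formed 3 separate clusters. Across genes, libraries of one group had Pearson correlations of log2 CPM from 0.967 to 0.994. The lowest values, 0.967 and 0.968, were those of *G. trabeum* high-melanin replicate 3 with the other 2 libraries of its group. No pair of libraries of one group agreed within sampling noise, the lowest chi-square per degree of freedom being 17.4, so all 18 were counted. Pairs across groups were not checked in this way.

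**Figure D1:**
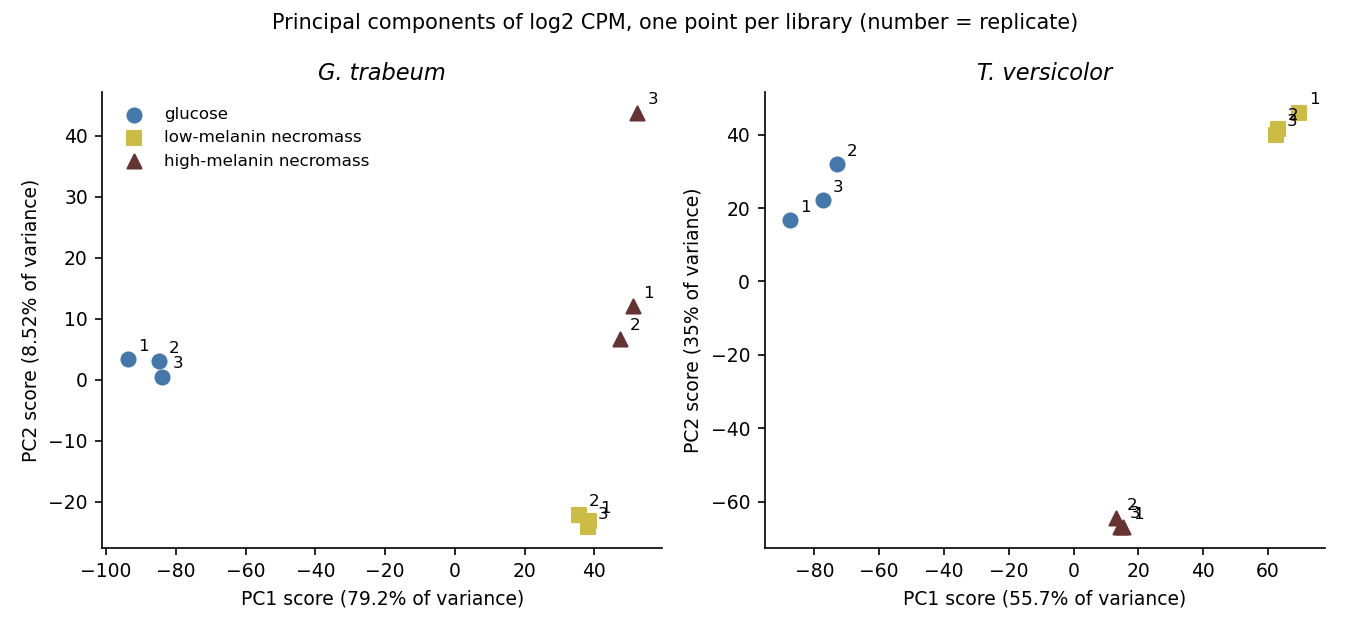
Scores of each library on the first (x axis) and second (y axis) principal component of log2 CPM, for *G. trabeum* (left) and *T. versicolor* (right), with 3 libraries per carbon source and the replicate number beside each point. The axes give the share of variance, 79.2% and 8.52% on the left and 55.7% and 35% on the right, and *G. trabeum* high-melanin replicate 3 lies apart from its group on the second component.

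On low-melanin necromass, 3004 genes of *G. trabeum* were higher and 2959 lower than on glucose among 10728 tested, with 1575 higher and 1216 lower by at least 2-fold. The genes at least 2-fold higher took 31.7% ± 0.68 of all counts on low-melanin necromass and 5.25% ± 0.17 on glucose (SD, n = 3). Those at least 2-fold lower fell from 32.8% ± 0.42 of counts on glucose to 8.62% ± 0.37 (SD, n = 3). Because these genes were chosen by the same comparison, the shares describe its size and are not a separate test. GLOTRDRAFT_96872 rose from 3.64 ± 2.0 CPM on glucose to 1290 ± 710 CPM (SD, n = 3), a log2 fold change of 8.48 ± 0.62 (SE) with an adjusted p of 2.85e-06 in edgeR's quasi-likelihood test. Part of its counts was divided between similar transcripts, so its level is uncertain. GLOTRDRAFT_127716 rose from 24.6 ± 11 to 7380 ± 99 CPM, a log2 fold change of 8.23 ± 0.58 (SE, adjusted p = 2.2e-06), and of 7.61 with fragment length as a covariate. GLOTRDRAFT_108386 went from 6180 ± 120 to 25.6 ± 2.6 CPM, a log2 fold change of -7.91 ± 0.25 (SE, adjusted p = 3.21e-08). GLOTRDRAFT_105906 went from 1410 ± 110 to 7.95 ± 1.0 CPM, a log2 fold change of -7.47 ± 0.31 (SE, adjusted p = 1.08e-07).

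On high-melanin necromass, 3180 genes of *G. trabeum* were higher and 3145 lower than on glucose, with 1701 higher and 1426 lower by at least 2-fold. The share of called genes that were higher was 50.3% with TMM, 57.1% by library size alone and 55.9% with upper-quartile scaling. The median log2 fold change of all genes moved from 0.03 to 0.13 and 0.11. The genes at least 2-fold higher took 33.4% ± 3.3 of counts on high-melanin necromass and 4.59% ± 0.32 on glucose (SD, n = 3). GLOTRDRAFT_127955 rose from 11 ± 5.8 to 5470 ± 3600 CPM (SD, n = 3), a log2 fold change of 8.96 ± 0.69 (SE, adjusted p = 3.43e-06). GLOTRDRAFT_127957 rose from 3.17 ± 1.6 to 1490 ± 1200 CPM, a log2 fold change of 8.88 ± 0.73 (SE, adjusted p = 4.89e-06). Both transcripts are 402 bases long and carried counts divided between similar transcripts, so the level of each is uncertain. Without high-melanin replicate 3 their log2 fold changes were 8.26 and 7.96, and with fragment length as a covariate 8.22 and 8.13. GLOTRDRAFT_108386, also named above for low-melanin necromass, went from 6180 ± 120 to 17.4 ± 3.7 CPM, a log2 fold change of -8.47 ± 0.25 (SE, adjusted p = 2.38e-08). GLOTRDRAFT_133652 went from 1220 ± 60 to 6.91 ± 0.91 CPM, a log2 fold change of -7.46 ± 0.31 (SE, adjusted p = 7.75e-08).

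The changes of *G. trabeum* on the necromass types were alike in direction. Of the 10728 genes tested, 2595 were higher and 2590 lower than on glucose on both types, and 30 were called in opposite directions. Leaving out glucose replicate 1, 2 or 3 each gave 15 such opposite genes, and fragment length as a covariate gave 12. The log2 fold changes on the 2 types had a Pearson correlation of 0.934 across genes, which are not independent replicates. Libraries simulated with no change, sharing their glucose libraries as here, gave a mean correlation of 0.501 and at most 0.568 in 100 draws. For unchanged genes the sharing alone sets such a value, so it does not tell which part of 0.934 comes from the shared libraries. The covariance was 1.575 against a simulated mean of 0.0328. Independent lists of these sizes would share 890 higher and 867 lower genes. The 3 glucose libraries do not give each comparison at least 2 of its own, so part of the excess of the overlap counts over independent lists may come from the shared controls. The simulated covariance already includes them, and the observed value exceeded it by 1.54.

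High-melanin and low-melanin necromass differed in fewer genes of *G. trabeum*: 221 were higher and 499 lower on the high-melanin type, or 6.71% of the genes tested. By at least 2-fold, 74 were higher and 257 lower. GLOTRDRAFT_131887 stood at 0.934 ± 0.58 CPM on glucose, 11.7 ± 4.0 on low-melanin and 106 ± 55 on high-melanin necromass (SD, n = 3), a log2 fold change of 3.18 ± 0.46 between the necromass types (SE, adjusted p = 0.00417). Its adjusted p ran from 1.3e-10 to 0.0501 over its alternatives, the highest being in the test beyond 2-fold, which also ended the calls of the next pair of genes (adjusted p = 0.389 and 0.0751). GLOTRDRAFT_107452 stood at 3.93 ± 0.58, 249 ± 160 and 1520 ± 1000 CPM in the same order, a log2 fold change of 2.61 ± 0.60 (SE, adjusted p = 0.0319). This call was lost without glucose replicate 2, low-melanin replicate 2, low-melanin replicate 3 or high-melanin replicate 3, with adjusted p of 0.0581, 0.0514, 0.0835 and 0.0797, and in a fit of only the 6 libraries compared, at 0.078, within a range of 0.000631 to 0.389. Its log2 fold change was 2.62, 3.05, 2.77 and 1.93 without those libraries and 2.62 in the fit of 6. GLOTRDRAFT_56292 was at 512 ± 140 CPM on glucose, 713 ± 290 on low-melanin and 39.6 ± 34 on high-melanin necromass, a log2 fold change of -4.17 ± 0.71 (SE, adjusted p = 0.00892). Without high-melanin replicate 1 its adjusted p was 0.0517, and without high-melanin replicate 2 its log2 fold change was -5.03. Over all alternatives its log2 fold change ran from -5.03 to -3.67 and its adjusted p from 1.48e-06 to 0.0751. GLOTRDRAFT_131906 was at 10.9 ± 3.5, 41.2 ± 24 and 2.62 ± 1.0 CPM, a log2 fold change of -3.97 ± 0.47 (SE, adjusted p = 0.00221). It was higher than glucose on the low-melanin type and lower on the high-melanin type, with log2 fold changes of 1.91 and -2.06 (adjusted p = 0.00358 and 0.00327).

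The *G. trabeum* counts between necromass types moved with the test and with single libraries. DESeq2 called 462 higher and 756 lower, 1218 in all, and a fit of only the 6 libraries compared called 117 and 324, or 441. By at least 2-fold, 112 were higher in DESeq2, 49 in the fit of 6 libraries and 121 by library size alone. Without low-melanin replicate 1, 2 or 3, 114, 123 and 113 genes were higher, and without high-melanin replicate 1, 97 were higher and 223 lower, 150 of them by at least 2-fold. Without low-melanin replicate 2, 325 were lower, and without high-melanin replicate 3, the library that stood apart, 198 were higher and 465 lower. Scaling by library size alone called 441 higher and 406 lower, so that 52.1% of the called genes were higher in place of 30.7%.

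**Figure D2:**
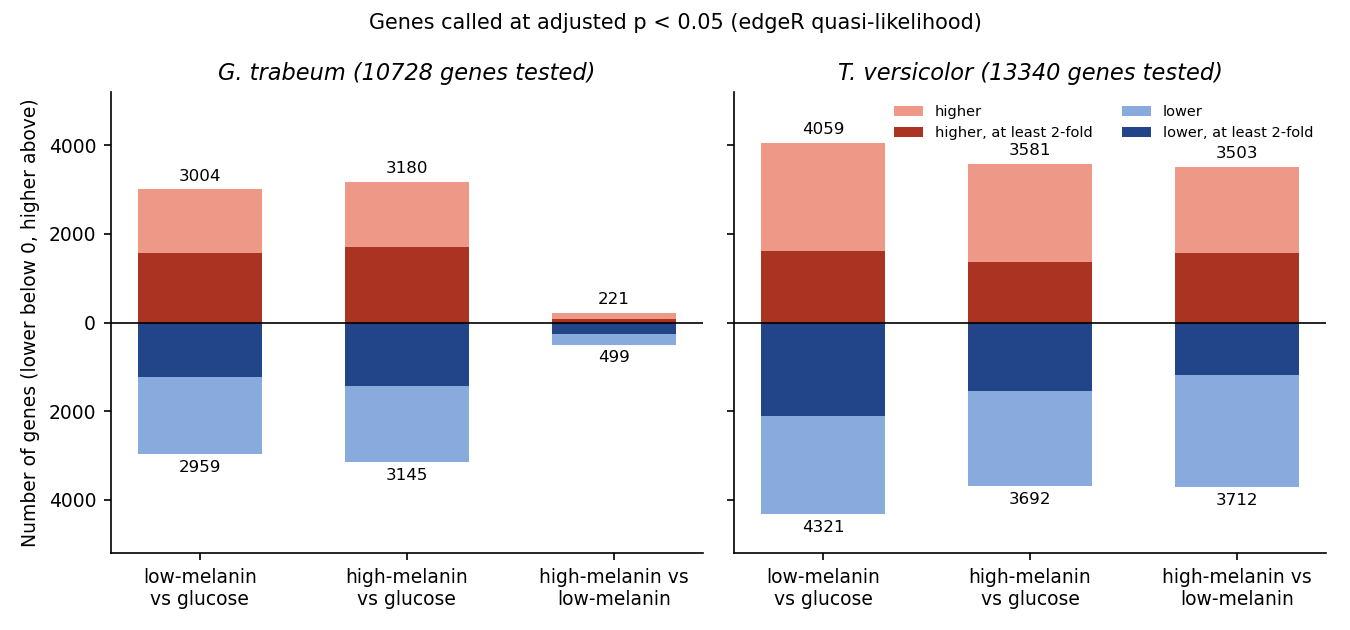
Number of genes (y axis) called higher (above 0) or lower (below 0) at an adjusted p under 0.05 in edgeR's quasi-likelihood test, for the 3 comparisons (x axis) of each fungus, with 3 libraries per group. Darker parts are genes changed by at least 2-fold. The bars for high-melanin against low-melanin necromass reach 221 and 499 genes in *G. trabeum* and 3503 and 3712 in *T. versicolor*.

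On low-melanin necromass, 4059 genes of *T. versicolor* were higher and 4321 lower than on glucose among 13340 tested, with 1616 higher and 2111 lower by at least 2-fold. The genes at least 2-fold higher took 34.6% ± 0.65 of counts on low-melanin necromass and 8.11% ± 0.34 on glucose (SD, n = 3). Gene jgi.p|Traver1|9732 rose from 6.45 ± 5.8 to 5360 ± 790 CPM (SD, n = 3), a log2 fold change of 9.68 ± 1.44 (SE, adjusted p = 0.00105), and of 10.7 without glucose replicate 2 and 7.51 with fragment length as a covariate. Gene jgi.p|Traver1|6536 rose from 7.61 ± 7.8 to 5840 ± 550 CPM, a log2 fold change of 9.57 ± 1.01 (SE, adjusted p = 0.000123), and of 10.83 without the same library, 10.2 in limma-voom and 7.98 with that covariate. Gene jgi.p|Traver1|6940 went from 1670 ± 600 to 5.40 ± 1.6 CPM, a log2 fold change of -8.27 ± 0.36 (SE, adjusted p = 1.23e-08). Gene jgi.p|Traver1|12178 went from 357 ± 360 to 1.14 ± 0.038 CPM, a log2 fold change of -8.28 ± 1.76 (SE, adjusted p = 0.00583). Its glucose counts ranged from 189 to 16421 between libraries, limma-voom did not call it (adjusted p = 0.138, within a range of 2.1e-11 to 0.138 over its alternatives), and its log2 fold change was -6.73 there, -7.21 without glucose replicate 3 and -13.51 with the covariate. With fragment length as a covariate 5517 genes were called in place of 8380, 2733 of them lower, and 60.6% of the calls were kept in the same direction. Mean fragment lengths were 291 to 344 bases on glucose and 249 to 274 on low-melanin necromass. As these ranges do not overlap, the covariate is hard to separate from the carbon source, and calls can be lost even if fragment length has no effect. The share of called genes that were higher depended on the scaling. It was 48.4% with TMM, 32.6% with upper-quartile scaling and 30.8% by library size alone, as the median log2 fold change of all genes moved from -0.04 to -0.28 and -0.32.

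On high-melanin necromass, 3581 genes of *T. versicolor* were higher and 3692 lower than on glucose, with 1358 higher and 1541 lower by at least 2-fold. The genes at least 2-fold higher took 30% ± 0.68 of counts on high-melanin necromass and 5.55% ± 0.32 on glucose (SD, n = 3). Gene jgi.p|Traver1|12457 rose from 7.58 ± 5.4 to 6080 ± 2600 CPM (SD, n = 3), a log2 fold change of 9.63 ± 0.64 (SE, adjusted p = 2.68e-06), and of 10.4 without glucose replicate 2 and 8.77 with fragment length as a covariate. Gene jgi.p|Traver1|4679 rose from 1.68 ± 0.98 to 628 ± 75 CPM, a log2 fold change of 8.52 ± 0.35 (SE, adjusted p = 6.7e-09). Gene jgi.p|Traver1|6940 was also lower here, at 4.44 ± 0.72 CPM, with a log2 fold change of -8.55 ± 0.37 (SE, adjusted p = 1.15e-08). Gene jgi.p|Traver1|12178 was at 0.727 ± 0.40 CPM, a log2 fold change of -8.88 ± 1.82 (SE, adjusted p = 0.00602). As on the other necromass type, limma-voom did not call it (adjusted p = 0.161, within a range of 7.83e-13 to 0.161), and its log2 fold change was -7.52 there, -7.82 without glucose replicate 3, -8.11 with the replicate number as a block and -12.13 with the covariate. With upper-quartile scaling 36.7% of the called genes were higher in place of 49.2%, as the median log2 fold change of all genes moved from -0.01 to -0.16, and by library size alone 40.8%, with a median of -0.11.

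In *T. versicolor*, 2190 genes were higher and 2362 lower than on glucose on both necromass types, and 722 were called in opposite directions. With fragment length as a covariate, which is hard to separate from the carbon source in this fungus, 353 were called in opposite directions. The log2 fold changes on the 2 types had a Pearson correlation of 0.627 across genes. Simulated unchanged libraries with shared glucose libraries gave a mean correlation of 0.494 and at most 0.530 in 100 draws. For unchanged genes the sharing alone sets such a value, so it does not tell which part of 0.627 comes from the shared libraries. The covariance was 0.925 against a simulated mean of 0.024. Independent lists of these sizes would share 1090 higher and 1196 lower genes. As in *G. trabeum*, part of the excess of the overlap counts over independent lists may come from the shared controls, while the covariance exceeded the simulated mean, which includes them, by 0.901.

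**Figure D3:**
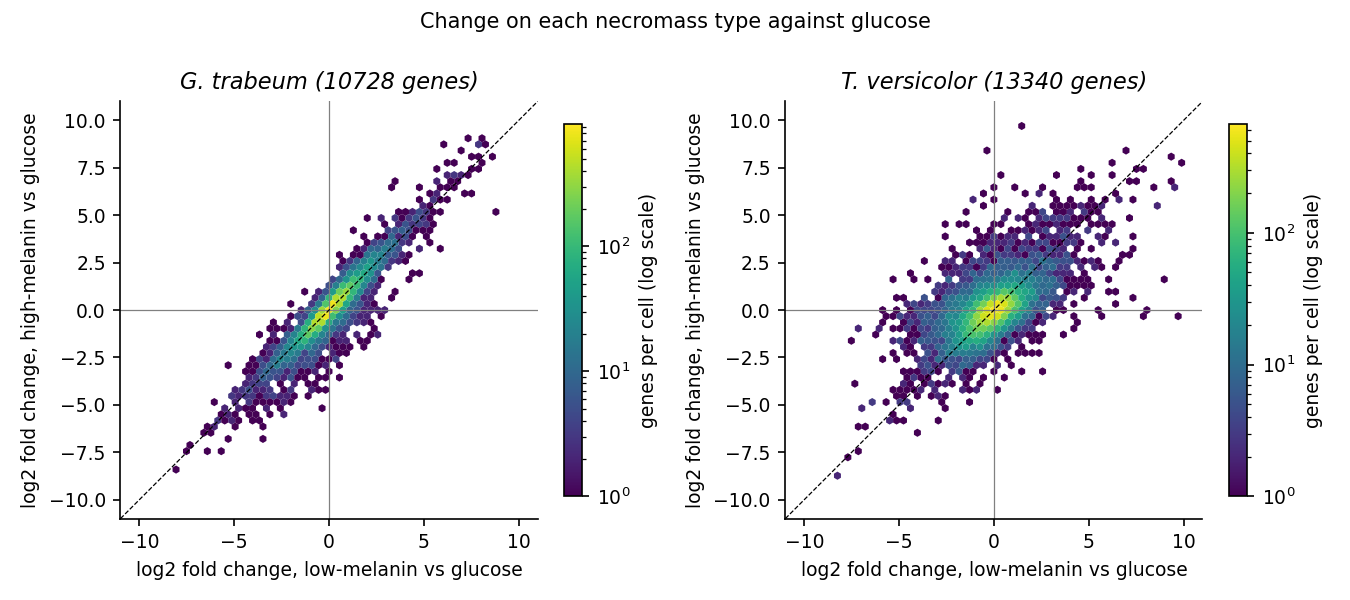
Log2 fold change of each tested gene on low-melanin necromass against glucose (x axis) and on high-melanin necromass against glucose (y axis), for *G. trabeum* (left, 10728 genes) and *T. versicolor* (right, 13340 genes). Colour gives the number of genes per cell on a log scale, and the dashed line marks equal changes. The correlation across genes was 0.934 on the left and 0.627 on the right.

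High-melanin and low-melanin necromass differed in 7215 genes of *T. versicolor*, 54.1% of those tested, with 3503 higher and 3712 lower on the high-melanin type. By at least 2-fold, 1576 were higher and 1190 lower. The genes at least 2-fold higher on the high-melanin type took 19.9% ± 0.60 of counts there and 3.82% ± 0.22 on the low-melanin type (SD, n = 3). Those at least 2-fold lower took 8.31% ± 0.22 and 25.8% ± 0.75. Gene jgi.p|Traver1|4700 stood at 20.3 ± 5.8 CPM on glucose, 15.6 ± 2.6 on low-melanin and 6360 ± 1600 on high-melanin necromass (SD, n = 3), a log2 fold change of 8.67 ± 0.31 between the necromass types (SE, adjusted p = 1.22e-09). Gene jgi.p|Traver1|12457, named above against glucose, stood at 19.0 ± 3.3 CPM on low-melanin necromass, and its log2 fold change between the types was 8.32 ± 0.61 (SE, adjusted p = 5.93e-06). In the other direction, jgi.p|Traver1|9732 was at 5360 ± 790 CPM on low-melanin and 4.52 ± 6.4 on high-melanin necromass, a log2 fold change of -10.18 ± 1.5 (SE, adjusted p = 0.00117), and of -12.69 without high-melanin replicate 1 and -11.3 in limma-voom. Gene jgi.p|Traver1|4386 was at 5.17 ± 2.3, 1400 ± 170 and 3.83 ± 2.1 CPM on glucose, low-melanin and high-melanin necromass, a log2 fold change of -8.49 ± 0.46 (SE, adjusted p = 3.83e-07). By library size alone 62.8% of the called genes were higher in place of 48.6%, as the median log2 fold change of all genes moved from -0.01 to 0.17.

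Genes of *T. versicolor* higher on one necromass type than on both other carbon sources were numerous. On low-melanin necromass 2290 genes were called higher than on glucose and than on high-melanin necromass. On high-melanin necromass 1568 were called higher than on glucose and than on low-melanin necromass. The same classes held 148 and 162 genes in *G. trabeum*. The class of 162 could hold at most 97 genes without high-melanin replicate 1 and 117 in the fit of 6 libraries. Those were all the genes called higher on high-melanin than on low-melanin necromass there. Counts of calls in the 2 fungi come from separate models over different gene sets, and no test of the difference between the fungi was made for single genes.

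**Figure D4:**
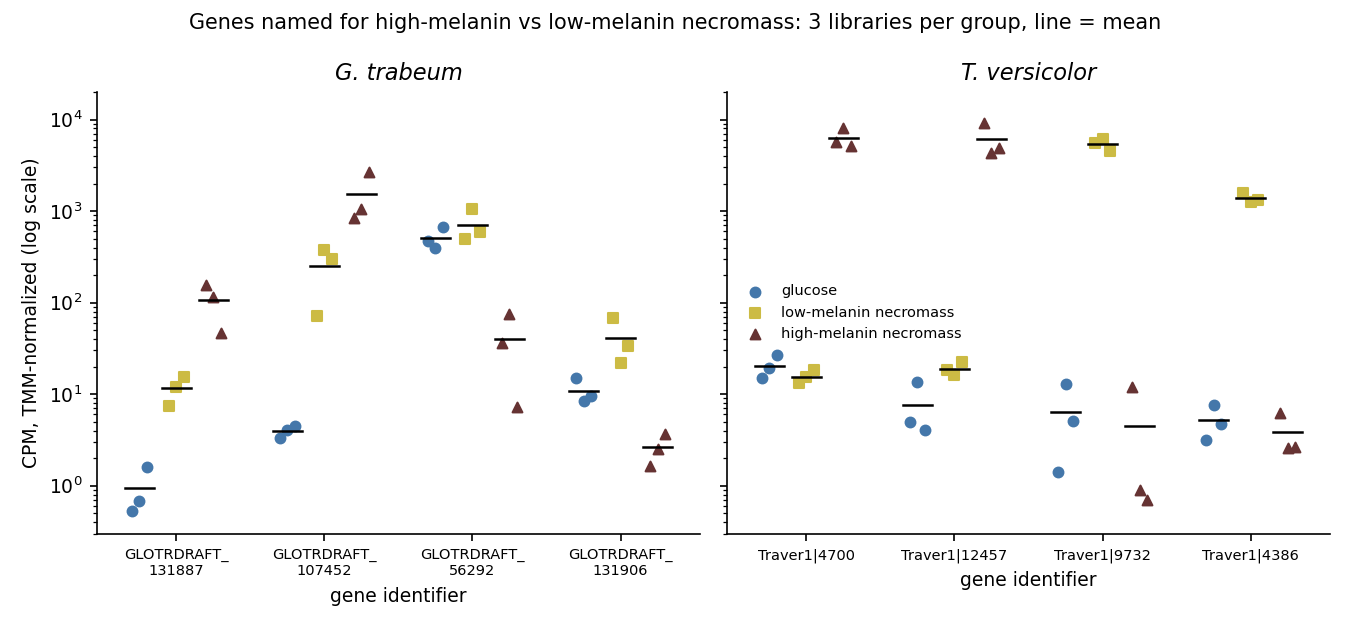
TMM-normalized CPM (y axis, log scale) of the genes (x axis) named for high-melanin against low-melanin necromass in *G. trabeum* (left) and *T. versicolor* (right). Each point is 1 library, with 3 per carbon source, and each line is the group mean. Gene jgi.p|Traver1|4700 reached a mean of 6360 CPM on high-melanin necromass against 20.3 on glucose and 15.6 on low-melanin necromass.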

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

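The thinning of libraries, and the counts at an unadjusted p and by limma-voom for the other splits, were tests chosen after seeing the data, and the numbers of called genes in the main test were known before any explanation was weighed. In *T. versicolor*, 722 genes were called in opposite directions against glucose on the 2 necromass types and were also called different between them. They stand out by the opposite calls. These make a called difference between the types nearly certain, so that call is not separate support. In *G. trabeum* 30 genes met the same conditions. With fragment length as a covariate, also chosen after seeing the data, 353 and 12 genes were called in opposite directions. In *T. versicolor* that covariate is hard to separate from the carbon source.

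The tRNA-type transcripts of *G. trabeum*, which take almost no part in the comparisons since 5 of 127 were tested, held 424 counts in high-melanin replicate 3. The glucose libraries held 148 to 180 and the other necromass libraries 118 to 206. One transcript, GLOTRDRAFT_t125, gave 180 of the 424 counts and 4 to 44 in each of the other libraries. It was singled out after its values were seen. The library is the one that stood apart from its group in the principal components.

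High-melanin against low-melanin necromass gave 720 called genes in *G. trabeum* and 7215 in *T. versicolor*, against 1218 and 7269 in DESeq2 and 441 and 8336 in fits of only the 6 libraries compared. Without *G. trabeum* high-melanin replicate 3, the library that stood apart, 663 genes were called, and 320 and 637 without replicates 1 and 2. Low-melanin necromass against glucose rose from 5963 to 6622 calls without replicate 3, so this library probably raised the shared spread. Leaving it out also lowers power. In *T. versicolor*, leaving out 1 high-melanin library still left 6241 to 6496 calls, which argues against that library as the whole cause. With every library thinned to the smallest, 7129 genes were called in *T. versicolor*, which argues against depth. The SD of log2 fold changes after removing the spread between replicates was 0.389 in *G. trabeum* and 1.02 in *T. versicolor*, and with each library left out in turn the ratio stayed at 2.46 or more, so larger replicate spread alone is unlikely as the whole cause. A weaker response of *G. trabeum* to the necromass type is a hypothesis that stays open. Differences in growth or in necromass use at day 7 also stay open and were not tested. The sample labels name the types by melanin only, so any other difference between them cannot be told apart from melanin content. No test set the 2 fungi against each other gene by gene.

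Other splits of the 6 libraries of each comparison were also fitted. In each of the 6 comparisons 1 of the 10 splits, the real one, gave as many genes as observed, and 10 splits are too few for a share under 0.05. The real splits called 5963, 6325 and 720 genes in *G. trabeum* and 8380, 7273 and 7215 in *T. versicolor*, in the order low-melanin against glucose, high-melanin against glucose and high-melanin against low-melanin. The highest other split called 0 genes in all 6 with edgeR and 0 with limma-voom. Every other split mixes both carbon sources in each group, so a carbon-source effect widens its spread and few calls are expected. No conclusion is drawn from those 0 counts. At an unadjusted p under 0.05 the highest other splits reached 143, 453 and 2064 genes in *G. trabeum*, where the real ones reached 6517, 6784 and 2160, and 515, 520 and 185 in *T. versicolor*, where the real ones reached 8897, 7900 and 7904. For high-melanin against low-melanin necromass in *G. trabeum*, another split thus came close to the real one in unadjusted calls. Deviations shared between these groups are given below, and whether they produced the calls of that split was not tested.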

How the results depend on the processing

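No log2 fold change of a named gene and no correlation between the necromass types changed sign under the settings tried, and no called gene of the main test was called in the opposite direction under any setting. Under the test beyond 2-fold, which asks for a larger change, *G. trabeum* had 902 higher and 714 lower genes on low-melanin necromass against glucose, 1032 and 901 on high-melanin necromass, and 3 and 30 between the types, with 783 higher and 624 lower on both and 0 opposite (30 in the main test). The 3 higher genes were GLOTRDRAFT_37518, GLOTRDRAFT_128236 and GLOTRDRAFT_82303. *T. versicolor* had 1070 and 1229, 862 and 767, and 925 and 581, with 474 and 418 on both and 42 opposite. Restricted to called genes at least 2-fold changed, 1325 were higher and 1063 lower on both types in *G. trabeum* and 740 and 901 in *T. versicolor*, with 4 and 123 opposite. The 4 were GLOTRDRAFT_52989, GLOTRDRAFT_121404, GLOTRDRAFT_131906 and GLOTRDRAFT_134059, all higher on low-melanin and lower on high-melanin necromass. For *G. trabeum* between necromass types, DESeq2 called 462 higher and 756 lower, a fit of only the 6 libraries compared 117 and 324, and library size alone 441 higher. With one library left out, 97 to 229 were higher and 223 to 465 lower, and opposite genes numbered 15 to 33. In *T. versicolor* library size alone gave 2699 higher on low-melanin necromass against glucose. Fragment length as a covariate, chosen after seeing the data like library size alone, is hard to separate from carbon source in *T. versicolor*. In that fungus it left 2733 lower on low-melanin necromass against glucose and 353 opposite genes, and in *G. trabeum* 12 opposite. Except where a stricter condition accounts for it, the cause was not tested. With the replicate number as a block, 133 genes of *G. trabeum* were higher between the types in place of 221, and no other of these counts moved by over 1.5 times. Same-numbered libraries did not deviate together, with correlations from -0.516 to 0.0795 in *G. trabeum* and -0.15 to 0.034 in *T. versicolor*, so the numbers were not taken to pair them. Differently numbered libraries ran from -0.314 to 0.456 in *G. trabeum* and from -0.0617 to 0.136 in *T. versicolor*. The highest values were those of *G. trabeum* low-melanin replicate 3 with high-melanin replicates 1 and 2, at 0.456 and 0.353. High-melanin replicate 3 went the other way, at 0.283 and 0.173 with low-melanin replicates 1 and 2 and -0.516 with low-melanin replicate 3. The necromass libraries of this fungus thus shared deviations across groups, which may affect the calls between the types. With fragment length as a covariate, 706 genes were called between the types and 88.8% of the main calls were kept. Whether another factor is shared by these libraries was not tested. The other 423 values for these counts and correlations stayed within 1.5 times or 0.1. For named genes, 536 values kept their call and 11 lost it. The alternatives for gene lists, list scores and ortholog pairs were not run, since no list or pair could be made. With 3 simulated libraries per group at these depths, 2-fold changes were called in 71.6% to 77.6% of genes. Thinning to the smallest library gave 705 calls in place of 720 between the types in *G. trabeum* and 7129 in place of 7215 in *T. versicolor*.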

Other observations

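The tests of gene order and of length were chosen before their results were seen, and the genes and runs named here after. Genes that neighbour each other in *G. trabeum* changed in runs, with scaffold borders inferred from falling start positions since the reference table names no scaffolds. On low-melanin necromass there were 32 runs of at least 4 adjacent genes all changed at least 2-fold in one direction against glucose, holding 156 genes, while the highest of 100 shuffled gene orders gave 12 runs. On high-melanin necromass there were 42 runs with 197 genes against 15. GLOTRDRAFT_117484 to GLOTRDRAFT_112083, a run of 8 genes, was lower on both types, with log2 fold changes of -2.42 to -1.23 on low-melanin and -3.08 to -1.20 on high-melanin necromass. The run of 6 genes from GLOTRDRAFT_53051 to GLOTRDRAFT_124422 was higher on both, by 1.80 to 3.38 and 1.43 to 3.25 on the log2 scale. Between the necromass types 3 runs were found, all lower on the high-melanin type, against 0 in the shuffled orders. They start at GLOTRDRAFT_141118, GLOTRDRAFT_123623 and GLOTRDRAFT_50888 and hold 5, 4 and 4 genes. Whether the last lies in repeated or ribosomal sequence was not tested.

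Across 10261 neighbouring pairs of *G. trabeum* genes, log2 fold changes on low-melanin necromass had a correlation of 0.185, and the highest of 1000 shuffled gene orders gave 0.035, which argues against a chance order. Over the 8141 pairs that do not overlap and carry whole counts alone the correlation was 0.166, which argues against reads shared between gene models as the whole cause. On high-melanin necromass the values were 0.193 and 0.181. Shared regulation of neighbouring genes is a hypothesis, and shared base composition or reads running from one gene into the next were not tested. In *T. versicolor*, genes with consecutive identifier numbers had correlations of 0.202, 0.173 and 0.215 in the 3 comparisons against at most 0.033 in shuffled orders, but whether those numbers follow the genome was not tested.

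Fold changes of *T. versicolor* against glucose followed coding length weakly. The Spearman correlation across 13340 genes was 0.102 on low-melanin and 0.132 on high-melanin necromass, and the median log2 fold change on low-melanin necromass was -0.15 among genes of at most 714 bases and 0.12 among those of at least 1740 bases. Fragments were shorter in the low-melanin libraries, which through the effective length would make short genes higher there, not lower as seen. This direction argues against fragment length acting through the effective length on low-melanin necromass. With the effective length of each library as an offset the correlations were larger, at 0.183 and 0.197. Given that direction the offset could only enlarge a positive correlation, so it is not a separate test. Other effects of RNA quality or of fragment size, and a biological difference between short and long genes, stay open. In *G. trabeum* the correlations were -0.01 and -0.02, but 68% of its lengths are multiples of 3, so they are not all coding lengths and the fungi are not directly comparable here.

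The run at GLOTRDRAFT_50888 holds 4 gene models of 180 to 420 bases whose joint share of counts differed between libraries of one group. On low-melanin necromass it was 3.93%, 0.801% and 0.218% in replicates 1, 2 and 3. On glucose it was 0.251% to 0.623%, and on high-melanin necromass 0.12% to 0.148%. All 4 were called lower on high-melanin than on low-melanin necromass.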
